A study of Homo sapiens with 6 samples.

How the data were processed

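The data are RNA-seq expression values of 6 libraries from cells labelled Huh7, 3 exposed to the HSP90 inhibitor 17-AAG and 3 controls. Per the labels' protocols, total RNA was extracted with TRIzol and sequenced from DNA nanoballs, the amplified circular molecules of that platform. The authors deposited 1 table of estimated counts per gene, as RSEM gives them, with 20013 genes named by symbol. Per the submitters' processing notes, the tools were Bowtie2 2.2.5 (alignment) and RSEM 1.2.12 (estimated counts per gene) and the genome build was hg38. The gene annotation, the strand setting, the read filters, the method of RNA selection and the dose and duration of 17-AAG are not given in the sources used here. The values in the table were whole numbers, so rounding for the count models changed nothing; whether the authors rounded them is not stated. RSEM divides reads between near-identical genes by a model, so values of close paralogs (HSPA1A and HSPA1B, AKR1C1 and AKR1C2, TUBB2A and TUBB2B, the SPANX and histone families, ribosomal protein genes and their pseudogenes) depend on that model. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart.

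Each column was assigned to its library by name, and each library to its group by the treatment in the labels. The series' design text speaks of 3 groups but names 17-AAG and control alone, which are also the only groups in the labels. No rows named something other than a gene. Counts of the same group differed by more than sampling noise in every pair of libraries (chi-square per gene from 1.70 to 2.17 between controls and from 19.7 to 117 between 17-AAG libraries), so no 2 were taken for 1 library deposited again; PCR duplicates add to such differences, so this does not show separate cultures. Library totals ranged from 15156386 to 16383054, and 3697 genes had no count in any library.

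Differential expression was tested in R 4.3.3 with edgeR 4.0.16: TMM scaling factors, filterByExpr at its defaults, dispersions by estimateDisp, and the quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided) of 17-AAG against control over the 6 libraries with group as the only term. It kept 12429 genes, which held 99.9% of all counts. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and called at an adjusted p below 0.05. The standard error is the absolute log2 fold change divided by the square root of F. CPM values are counts scaled to the TMM-adjusted library size, except for the hepatocyte genes below the filter, which are scaled to the total. Shares of library counts were compared by exact permutation tests over all 20 assignments.

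Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over 28 of the 29 lists. The same test with an estimated correlation, and fry, served as alternatives. The lists covered HSF1 targets, HSP90 co-chaperones and clients, p53 targets, G1/S, G2/M, senescence, secretory, lipid, stress, hepatocyte, proteasome, autophagy, apoptosis, glycolysis, interferon, cytoskeletal, immediate-early, mitochondrial, ribosomal and histone genes and markers of other cell types; 17 genes stood in more than 1 list. Lists, groups, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes 8 genes named for the study's question, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap (unnamed loci left out), and from each list up to 4 called members with the smallest adjusted p. Some genes the rule takes are not reported here. Other list members are named where the text describes an exception or a known regulator, and those were chosen after their values were seen. Coordinates, and the length and GC content of each gene's longest transcript, come from GENCODE release 29 on GRCh38.

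The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors (RLE, upper quartile, library size alone), other low-count filters, a stricter adjusted p of 0.01, a test against a fold change of 1.5, the replicate number as a block, and each library left out. Added after the data were seen were 17-AAG replicate 1 alone against the controls, per-library trends on transcript length and GC content as offsets (fitted with mgcv 1.9.3 on 12396 genes with a length and GC value, 99.7% of those tested), those offsets with the replicate block, and mitochondrial genes left out. The pipeline was tested on counts simulated for 12429 genes, as given with the results. A second simulation had no changed gene but a length and GC trend, the same in each 17-AAG library. Without the offsets 7541 genes were called, and 0 with them. Before the offsets the trend correlated at 0.957 with the fold changes. It ran opposite in sign to the data for length and for GC content. The trend was built from the values that the offsets fit, so the result does not show how they act on these data.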

Results

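RNA was sequenced from cells labelled Huh7, a line established from a human hepatocellular carcinoma, in 6 libraries. In 3 of them the cells had been exposed to 17-AAG (tanespimycin), a geldanamycin derivative that occupies the ATP pocket of the chaperone HSP90, and 3 were labelled controls. The dose and the length of the exposure are not given in the sources used here. The study's title sets the work in a question about HSF1, the transcription factor that drives heat-shock genes, about the HSP90α protein and p53, and about hepatocellular carcinoma cells that regrow after senescence, so the comparison asks how expression changed when HSP90 was inhibited. The deposited table lists 20013 genes. Its estimated counts summed to 16045059, 15225265 and 15156386 in 17-AAG replicates 1, 2 and 3, and to 16367290, 16238490 and 16383054 in control replicates 1, 2 and 3. A floor of 3 counts corresponded to 0.183 to 0.198 in counts scaled to library size (CPM); such floors cover counting error only, because PCR duplicates are not independent molecules. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

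The libraries of the 2 groups separated along the first principal component of log2 CPM, which held 77.0% of the variance, and the 17-AAG libraries differed more from each other than the controls did. Counts in mitochondrially encoded genes made up 7.21%, 19.3% and 11.3% of 17-AAG replicates 1, 2 and 3 and between 6.10% and 6.53% of the controls (12.6% ± 6.16 against 6.33% ± 0.216, SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Cytosolic ribosomal protein genes took 2.22% ± 0.370 of the counts with 17-AAG and 3.36% ± 0.0372 in the controls (SD, n = 3 each; exact two-sided permutation p = 0.1).

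**Figure D1:**
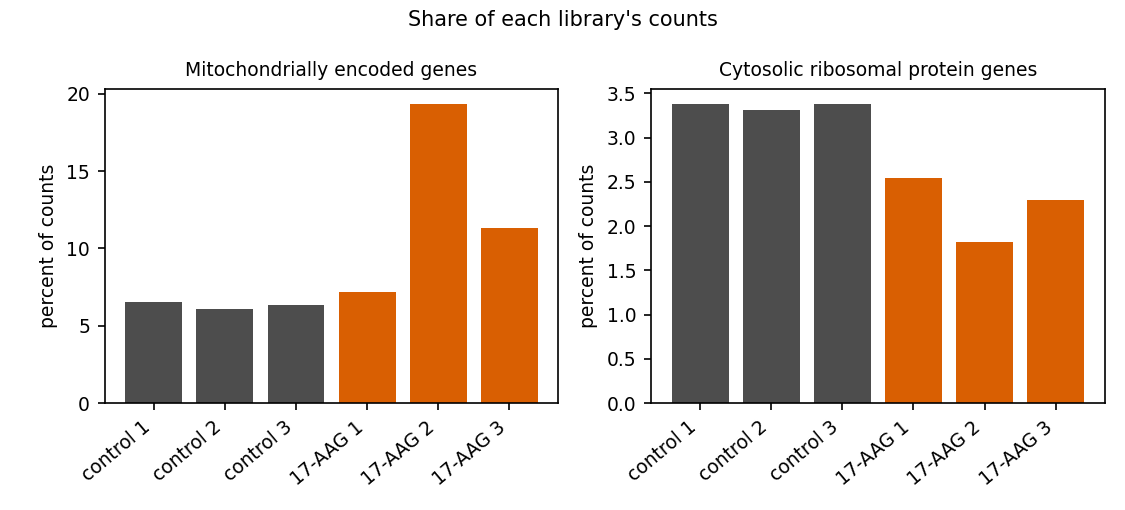
Percent of each library's counts in mitochondrially encoded genes (left) and in cytosolic ribosomal protein genes (right), 1 bar per library, controls in grey and 17-AAG in orange. The mitochondrial share of 17-AAG replicate 2 is 19.3%, against at most 6.53% in a control.

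Exposure to 17-AAG was accompanied by higher transcripts of HSP90 itself and of its heat-shock partners. HSP90AA1, which encodes the inducible HSP90α, rose 2.85-fold, from 878 ± 17.5 to 2502 ± 368 CPM (SD, n = 3 each; log2 fold change 1.51, SE 0.11, adjusted p = 5.52e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HSP90AB1, the constitutive HSP90β, rose 1.61-fold to 3477 ± 266 CPM (log2 fold change 0.69, SE 0.090, adjusted p = 0.00053). The HSP70 genes HSPA1A and HSPA1B rose 5.69-fold and 4.36-fold (log2 fold changes 2.51, SE 0.077, and 2.13, SE 0.15; adjusted p = 1.76e-06 and 4.37e-05); their sequences are near-identical, so the division of reads between them is uncertain. DNAJB1, an HSP40 co-chaperone, rose 1.36-fold, from 129 ± 2.73 to 175 ± 13.7 CPM (log2 fold change 0.44, SE 0.077, adjusted p = 0.00209). HSF1 moved the other way and by less, from 128 ± 2.75 to 106 ± 10.7 CPM (log2 fold change -0.27, SE 0.085, adjusted p = 0.0283). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 1.74-fold from 56.9 ± 3.47 to 98.9 ± 11.7 CPM (log2 fold change 0.80, SE 0.10, adjusted p = 0.000445). The HSF1 call ended when trends on transcript length and GC content were removed (log2 fold change -0.046, adjusted p = 0.679) and when any control library was left out (adjusted p from 0.0669 to 0.0930); over its alternatives it ranged from 0.00721 to 0.679. The fit with 17-AAG replicate 1 alone, in which only the controls give a spread, is left out of this range and of those below. Under scaling by library size alone the DNAJB1 call ended (adjusted p = 0.0639; 3.56e-07 to 0.0772 over its alternatives).

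**Figure D2:**
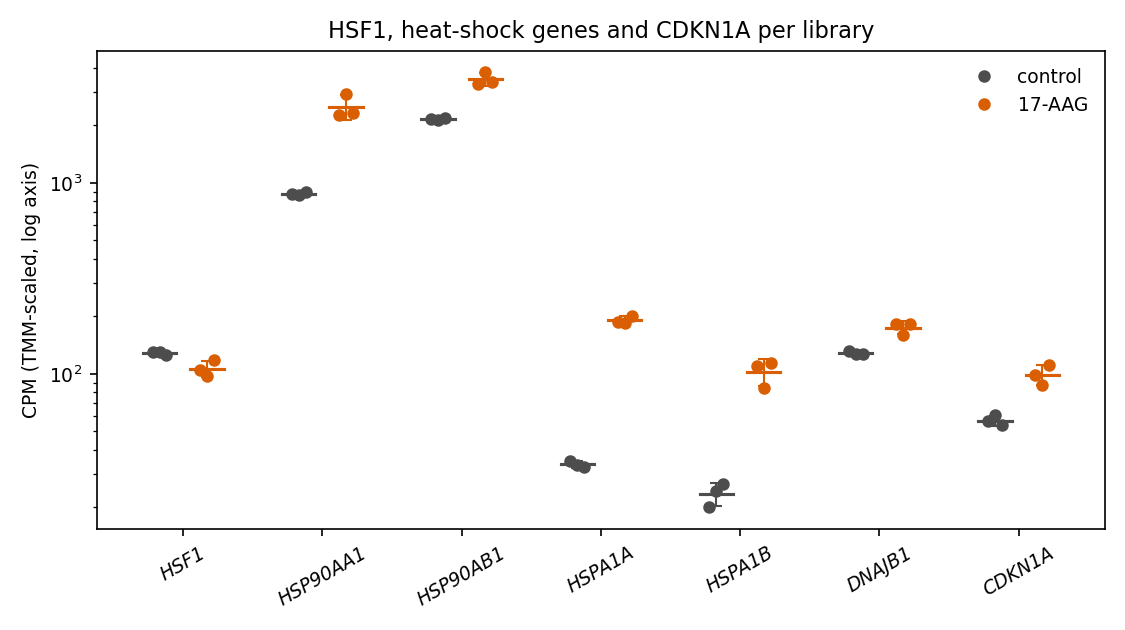
CPM (TMM-scaled, log axis) of 7 genes in the 6 libraries. Points are libraries, horizontal lines the group means and error bars the SD (n = 3), controls in grey and 17-AAG in orange; HSP90AA1 lies at 878 CPM in the controls and 2502 CPM with 17-AAG, and HSF1 at 128 and 106 CPM.

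All of these are annotated as protein-coding genes, and a gene's value sums reads over its transcripts. On GRCh38 (GENCODE release 29), HSF1 lies on chromosome 8 from 144291591 to 144314722 and HSP90AA1 on chromosome 14 from 102080738 to 102139699. HSP90AB1 lies on chromosome 6 from 44246166 to 44253888, CDKN1A on chromosome 6 from 36676460 to 36687339, HSPA1A on chromosome 6 from 31815464 to 31817946 and HSPA1B on the same chromosome from 31827735 to 31830255. DNAJB1 lies on chromosome 19 from 14514770 to 14529770.

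The response was wide. Of 12429 genes tested, 6359 (51.2%) changed at adjusted p below 0.05, of which 3212 were higher and 3147 lower with 17-AAG. Of the called genes, 3093 differed by less than 1.5-fold and the median size over called genes was 0.60 on the log2 scale, while 1168 changed at least 2-fold (633 higher, 535 lower). The groups did not overlap in 7884 tested genes (63.4%, where chance gives 10% for 3 against 3). The balance of directions depended on the scaling. With library size alone, which lowered the median log2 fold change of all tested genes to -0.13, 5860 genes were called and 36.8% of them were higher, against 50.5% with TMM factors; the changes below are relative to the TMM scale.

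Among genes with a mean of at least 5 CPM, the 8 largest rises were led by SPANXB1, a cancer-testis gene of a family with near-identical copies (chromosome X, 141002591 to 141003706), which went from 1.52 ± 0.232 to 30.1 ± 5.30 CPM (19.7-fold, log2 fold change 4.30, SE 0.19). CREB3L3, a membrane-bound transcription factor of hepatic lipid metabolism (chromosome 19, 4153601 to 4173054), rose 11.3-fold, with a wide spread between the 17-AAG libraries (33.7 ± 14.6 CPM). CGA, the common alpha subunit of the glycoprotein hormones (chromosome 6, 87085498 to 87095406), went from 48.1 ± 1.24 to 385 ± 19.5 CPM. TUBB2A, a beta-tubulin that shares sequence with TUBB2B (chromosome 6, 3153669 to 3157526), rose 7.32-fold. CPZ, EHF and ACTG2 rose between 5.93-fold and 6.41-fold, and HSPA1A completed the 8. The largest fall was that of PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (chromosome 14, 24094053 to 24110598), from 93.6 ± 4.0 to 14.4 ± 4.05 CPM (6.45-fold, log2 fold change -2.69, SE 0.18). INHBE, an activin subunit gene (chromosome 12, 57452323 to 57459280), fell 5.27-fold. The other falls were those of TEF, HSD17B8, TMEM160, CBS (cystathionine beta-synthase, of the transsulfuration pathway), MFSD3 and POU5F1B, by 4.28-fold to 4.72-fold. Adjusted p lay at or below 0.000435 for each of these 16 genes (edgeR, n = 3 each).

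The heat-shock response rose as a group. Of 24 tested HSF1 heat-shock targets, 22 rose and none fell, the same counts when adjusted over the list alone (median log2 fold change 0.70; camera adjusted p = 1.36e-09 with a preset correlation and adjusted p = 0.0734 with an estimated correlation). HSPH1 (HSP110) rose 3.07-fold from 152 ± 1.67 to 468 ± 25.1 CPM, HSPA8 (HSC70) 2.88-fold to 1538 ± 196 CPM, and BAG3, a co-chaperone of HSP70, had a log2 fold change of 1.27 (SE 0.092). HSPE1 and DNAJB6 did not pass the test, with log2 fold changes of 0.09 and 0.10. Of 20 tested HSP90 co-chaperones and paralogs 12 rose and 3 fell, also when adjusted over the list alone (median 0.54; camera adjusted p = 0.00989, and adjusted p = 0.206 with an estimated correlation). The members that rose included STIP1 (HOP, 1.79-fold), CHORDC1 (1.76-fold), FKBP4 (122 to 195 CPM) and AHSA1 (AHA1, which stimulates the HSP90 ATPase; 1.57-fold). The 3 that fell were TRAP1, the mitochondrial HSP90 paralog, PTGES3 (p23) and STUB1 (CHIP). That list's call ended when genes of more than 1 list were left out (adjusted p = 0.199; 0.00312 to 0.206 over its camera alternatives). HSP90 client kinases and receptors went both ways, with 7 of 26 higher and 9 lower (also over the list alone; median -0.06, camera adjusted p = 0.858): CDK4 fell 2.41-fold from a mean of 168 CPM to 69.4 ± 17.8 CPM, IKBKB and the glucocorticoid receptor gene NR3C1 fell 1.58-fold and 1.49-fold, and RIPK1 rose 2.03-fold.

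**Figure D3:**
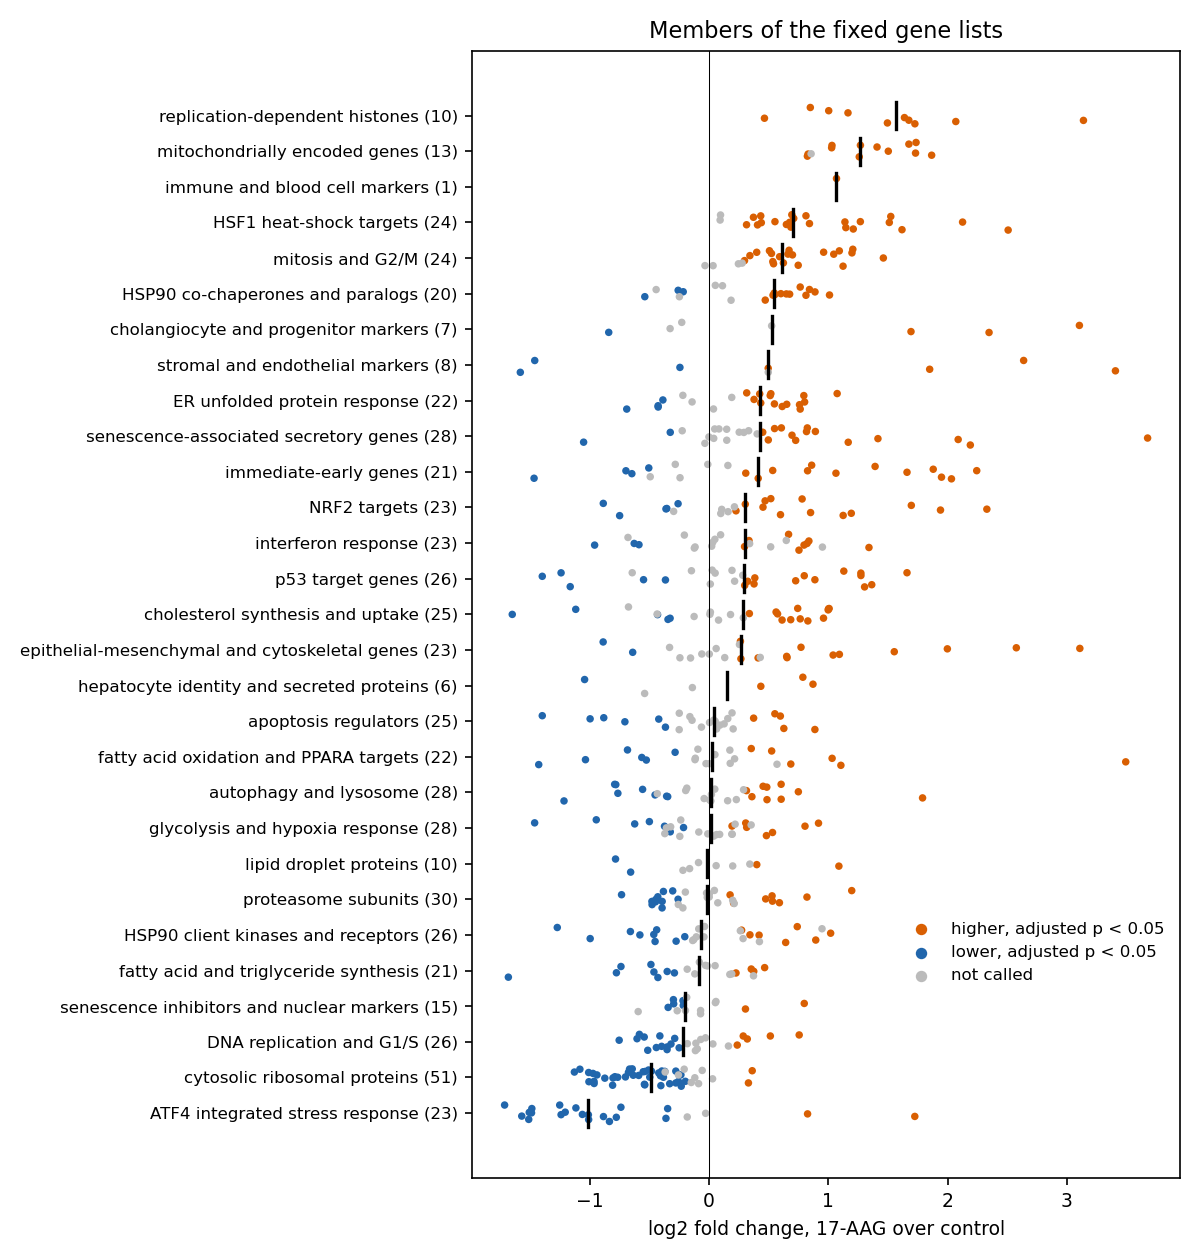
Log2 fold change (17-AAG over control) of each tested member of the 29 gene lists, with the number tested in parentheses; orange and blue points passed an adjusted p below 0.05, grey points did not, and black bars are list medians. The medians run from -1.01 for the ATF4 integrated stress response to 1.57 for the replication-dependent histones.

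Genes that p53 is known to induce were split. Of 26 tested p53 targets, 13 rose and 5 fell, the same when adjusted over the list alone, with a median log2 fold change of 0.29; as a set they did not pass the test (camera adjusted p = 0.0523, and adjusted p = 0.367 with an estimated correlation). BTG2, an antiproliferative gene, rose 3.16-fold, PLK2 2.47-fold and CDKN1A as above, and MDM2, the ubiquitin ligase of p53, had a log2 fold change of 0.33 (SE 0.081). DDB2, a DNA damage recognition factor, fell 2.24-fold from 88.7 ± 2.24 to 39.6 ± 4.24 CPM and SESN2, a sestrin, 2.36-fold. The set passed the threshold under library size alone (adjusted p = 0.0192), with length and GC trends removed (0.0228), and without 17-AAG replicate 2 (0.0250) or control replicate 2 (0.0475); over its camera alternatives the adjusted p ranged from 0.0192 to 0.367.

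Senescence-related genes did not move as a single group. Among 15 senescence inhibitors and nuclear markers 2 rose and 5 fell, also over the list alone (median -0.20; camera adjusted p = 0.286): CDKN1A rose, while CDKN1B (p27), the lysosomal beta-galactosidase gene GLB1 and CDKN2C (p18) fell by 1.27-fold, 1.23-fold and 1.23-fold. The lamin gene LMNB1, whose loss accompanies senescence, had a log2 fold change of -0.07 (adjusted p = 0.392). The calls of GLB1 and CDKN2C ended without control replicate 1 or 2, and that of CDKN2C also without control replicate 3 (adjusted p from 0.0606 to 0.0880; over their alternatives 0.000851 to 0.0642 for GLB1 and 0.00962 to 0.0880 for CDKN2C). Senescence-associated secretory genes were higher as a set, with 14 of 28 up and 2 down, also over the list alone (median 0.43; camera adjusted p = 0.000926, and adjusted p = 0.206 with an estimated correlation). ICAM1, an adhesion molecule, rose 2.25-fold to 80.5 ± 7.95 CPM, TIMP2 1.76-fold to 373 ± 28.4 CPM, and the interleukin genes IL1B and IL1A rose 4.25-fold and 2.67-fold from 1.21 and 3.13 CPM.

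The 2 lists of cell-cycle genes had medians of opposite sign. Of 24 tested genes of mitosis and G2/M, 20 rose and none fell, also over the list alone (median 0.61; camera adjusted p = 7.34e-07, and adjusted p = 0.206 with an estimated correlation). The kinase gene AURKA rose 2.31-fold from 77.9 ± 4.80 to 180 ± 22.7 CPM, the kinesin gene KIF20A 2.18-fold, the spindle checkpoint gene BUB1 1.95-fold and the ubiquitin-conjugating enzyme gene UBE2C 1.59-fold. Of 26 genes of DNA replication and G1/S, 5 rose and 13 fell, and 14 fell when adjusted over the list alone; the set did not pass the test (median -0.21; camera adjusted p = 0.0786). The replicative helicase subunits MCM6, MCM5 and MCM3 fell by 1.68-fold, 1.52-fold and 1.43-fold and the helicase cofactor CDC45 went from 65.3 to 43.6 CPM, while the cyclin E genes CCNE1 and CCNE2 rose, with log2 fold changes of 0.51 and 0.76. All 10 tested replication-dependent histone genes rose, also over the list alone (median 1.57; camera adjusted p = 1.02e-05, and adjusted p = 0.173 with an estimated correlation), among them H2BC12 from 20.4 ± 1.23 to 63.4 ± 6.56 CPM and H1-2 from 13.7 ± 1.09 to 27.5 ± 3.68 CPM. Histone genes are multicopy, and their transcripts mostly lack poly(A) tails.

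Genes of the ATF4 arm of the integrated stress response fell, while more genes of the endoplasmic reticulum's unfolded protein response rose than fell. Of 23 tested genes of the ATF4 list, 19 fell (20 over the list alone) and 2 rose (median -1.01; camera adjusted p = 1.29e-06, and adjusted p = 0.206 with an estimated correlation). ASNS, asparagine synthetase, fell 2.80-fold from 331 ± 5.93 to 118 ± 3.84 CPM. PSAT1, of serine synthesis, fell 2.85-fold from 723 ± 11.6 to 254 ± 21.3 CPM, STC2 3.28-fold and the mitochondrial folate enzyme gene MTHFD2 2.38-fold. ATF4 itself had a log2 fold change of -0.83 (SE 0.076); the 2 that rose were ATF5 and ATF3. Of 22 genes of the unfolded protein response, 14 rose and 4 fell (15 and 5 over the list alone; median 0.43, camera adjusted p = 0.0167, and adjusted p = 0.206 with an estimated correlation). HSPA5 (BiP) rose 1.74-fold from 1252 ± 14.8 to 2183 ± 44.4 CPM, CALR (calreticulin) 2.11-fold to 1603 ± 148 CPM, HSP90B1 (GRP94, the reticulum's HSP90) 1.70-fold and SEC24D 1.69-fold. The members that fell included DNAJB9, HERPUD1 and XBP1, with log2 fold changes of -0.69, -0.43 and -0.39. NRF2 targets, of the antioxidant response, rose in 13 of 23 cases and fell in 5, also over the list alone (median 0.30; camera adjusted p = 0.0167, and adjusted p = 0.373 with an estimated correlation). HMOX1, haem oxygenase, rose 3.84-fold to 131 ± 25.2 CPM, EPHX1 2.29-fold and PGD 1.72-fold; AKR1C1 rose 5.02-fold, but shares reads with its close paralog AKR1C2.

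In lipid metabolism, cholesterol synthesis and uptake genes were higher, with 12 of 25 up and 5 down, also over the list alone (median 0.29; camera adjusted p = 0.0433, and adjusted p = 0.291 with an estimated correlation). SQLE (squalene epoxidase) rose 2.01-fold, IDI1 rose from 39.1 to 78.3 CPM, and HMGCS1 rose 1.95-fold to 291 ± 19.2 CPM. That list's call ended without 17-AAG replicate 1 (adjusted p = 0.102) or 3 (0.0551) and without genes of more than 1 list (0.0512); the range over its camera alternatives was 0.0192 to 0.291. No call was made for the other lipid lists. For fatty acid and triglyceride synthesis 4 of 21 genes rose and 8 fell (median -0.08; camera adjusted p = 0.426), including MLXIPL (ChREBP, 3.21-fold lower) and the desaturase genes FADS1 (1.71-fold lower) and FADS2 (1.38-fold lower), with ELOVL5 1.38-fold higher. For lipid droplet proteins 2 of 10 rose and 2 fell (median -0.01; camera adjusted p = 0.962): PLIN2, a coat protein of lipid droplets, rose 2.13-fold and MGLL 1.32-fold, while HILPDA and the lipase gene LIPE fell 1.72-fold and 1.58-fold. MGLL lost its call under library size alone (adjusted p = 0.154; 3.98e-07 to 0.172 over its alternatives). For fatty acid oxidation and PPARA targets 6 of 22 rose and 6 fell (median 0.03; camera adjusted p = 0.858), with PDK4 2.04-fold higher and the trifunctional protein genes HADHA and HADHB 1.48-fold and 1.61-fold lower. Adjusting over each list alone left the counts of these 3 lists the same.

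Cytosolic ribosomal protein genes fell, while mitochondrially encoded genes rose. Of 51 cytosolic ribosomal protein genes, 41 fell and 2 rose, also over the list alone (median -0.48; camera adjusted p = 2.88e-08, and adjusted p = 0.266 with an estimated correlation). RPS18 fell 2.12-fold from 875 ± 7.04 to 414 ± 61.2 CPM, RPL3 1.96-fold from 1345 ± 24.5 to 686 ± 98.7 CPM, RPL37A 1.73-fold and RPL13A 1.56-fold; RPL12 and RPL28 rose. The list's median log2 difference from the controls was -0.40, -0.61 and -0.45 in 17-AAG replicates 1, 2 and 3. Ribosomal protein genes have many processed pseudogenes with which they share reads. Of 13 mitochondrially encoded genes 12 rose, and 13 over the list alone (median 1.27, camera adjusted p = 0.00817, and adjusted p = 0.581 with an estimated correlation). By fry the list did not pass (adjusted p = 0.103). The genes of this set are those that make up the libraries' mitochondrial share, so both move together by construction. The set's median log2 difference from the controls was 0.43 in 17-AAG replicate 1, 1.96 in replicate 2 and 1.05 in replicate 3. MT-ND5 rose 3.19-fold to 7541 ± 5037 CPM, MT-ND6 3.65-fold, MT-ATP8 2.66-fold and MT-ND4L 2.41-fold. Without 17-AAG replicate 2 the list's median was 0.82, and MT-ND5 and MT-ND6 had log2 fold changes of 0.99 and 1.09, against 1.68 and 1.87 with it.

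Immediate-early genes, the first to respond to many stimuli, were higher, with 12 of 21 up and 4 down (5 down over the list alone; median 0.41, camera adjusted p = 0.0222, and adjusted p = 0.395 with an estimated correlation). JUN rose 2.09-fold, ZFP36 3.68-fold and the kinase gene SGK1 2.62-fold, whereas MYC and EGR1 fell, with log2 fold changes of -0.65 and -1.47. The call ended when genes of more than 1 list were left out (adjusted p = 0.0842; 0.00355 to 0.395 over its camera alternatives). Epithelial-mesenchymal and cytoskeletal genes rose in 12 of 23 cases and fell in 2 (3 over the list alone; median 0.27, camera adjusted p = 0.0305, and adjusted p = 0.316 with an estimated correlation). The transcription factor genes SNAI1 (1.77 to 10.6 CPM) and SNAI2 (13.7 to 40.4 CPM), the myosin light chain gene MYL9 (45.2 to 181 CPM) and THBS1 (2.13-fold) rose, while N-cadherin, CDH2, had a log2 fold change of -0.89. Without 17-AAG replicate 2 that set did not pass (adjusted p = 0.0528), nor with length and GC trends removed (0.0505); the range over its camera alternatives was 0.0195 to 0.316.

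5 further lists gave no call as sets. Interferon response genes rose in 8 of 23 cases and fell in 3 (median 0.30; camera adjusted p = 0.120), with the antiviral genes OAS1, OAS2 and OAS3 1.74-fold, 2.53-fold and 1.77-fold higher and IFIH1 1.79-fold higher. Proteasome subunits split into 8 higher and 11 lower of 30 (9 and 13 over the list alone; median -0.02, camera adjusted p = 0.858), PSMD12 being 1.77-fold and PSMD11 1.51-fold higher. Autophagy and lysosome genes split into 9 and 8 of 28 (10 and 8 over the list alone; median 0.02, camera adjusted p = 0.858): the cathepsin gene CTSL rose 3.46-fold to 533 ± 59.3 CPM and the autophagy receptor gene SQSTM1 1.68-fold, and TFE3, a lysosomal transcription factor, fell 1.70-fold. Apoptosis regulators split into 5 and 6 of 25 (median 0.04; camera adjusted p = 0.962), with the BH3-only genes PMAIP1 (NOXA) 1.63-fold and BIK 1.99-fold lower and the antiapoptotic MCL1 1.34-fold lower. Glycolysis and hypoxia genes split into 7 and 7 of 28 (median 0.02; camera adjusted p = 0.858), with CA9, a hypoxia-induced carbonic anhydrase, 2.75-fold lower, ENO1 and GAPDH 1.54-fold and 1.41-fold lower, and PFKFB4 1.75-fold higher. For the interferon, apoptosis and glycolysis lists the counts over the list alone were the same. The medians of the last 4 of these lists, and of the lipid droplet, HSP90 client and fatty acid oxidation lists, lay within 0.1 of 0; under library size alone those of the autophagy, apoptosis, glycolysis and fatty acid oxidation lists were negative. Signs also differed between the median and the mean log2 fold change for the HSP90 client (-0.06 and 0.02), lipid droplet (-0.01 and 0.02), apoptosis (0.04 and -0.07) and glycolysis lists (0.02 and -0.05); the direction of camera's test was down for the HSP90 client, lipid droplet and glycolysis lists and up for the apoptosis list.

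Hepatocyte genes lay near the count floor in both groups. Of 33 hepatocyte identity and secreted-protein genes, 28 lay below 1 CPM in all 6 libraries, 17 had at most 3 counts in all, and the control libraries' medians were 0. ALB, the albumin gene, had no count among 95415544 counts, which allows up to 0.0314 CPM; APOA1 had 2 counts in all, AFP 4 and SERPINA1 3. 4 transcripts reached 1 CPM in every library, the transcription factors HNF4A, FOXA1 and CEBPA and the retinol carrier RBP4. Of the 6 that could be tested, 3 rose and 1 fell, also over the list alone (median 0.15; camera adjusted p = 0.620): RBP4 1.83-fold, FOXA1 1.73-fold and HNF4A 1.35-fold higher and CYP2E1 lower, from 2.02 to 1.00 CPM. The HNF4A call ended under library size alone (adjusted p = 0.145), without 17-AAG replicate 1 or 3 (0.0572 each) and without control replicate 1 (0.119) or 3 (0.101), with a range of 0.0112 to 0.238 over its alternatives. The CYP2E1 call ended without any control library and without 17-AAG replicate 1 or 3 (adjusted p from 0.0516 to 0.126, within 0.00144 to 0.126 over its alternatives).

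**Figure D4:**
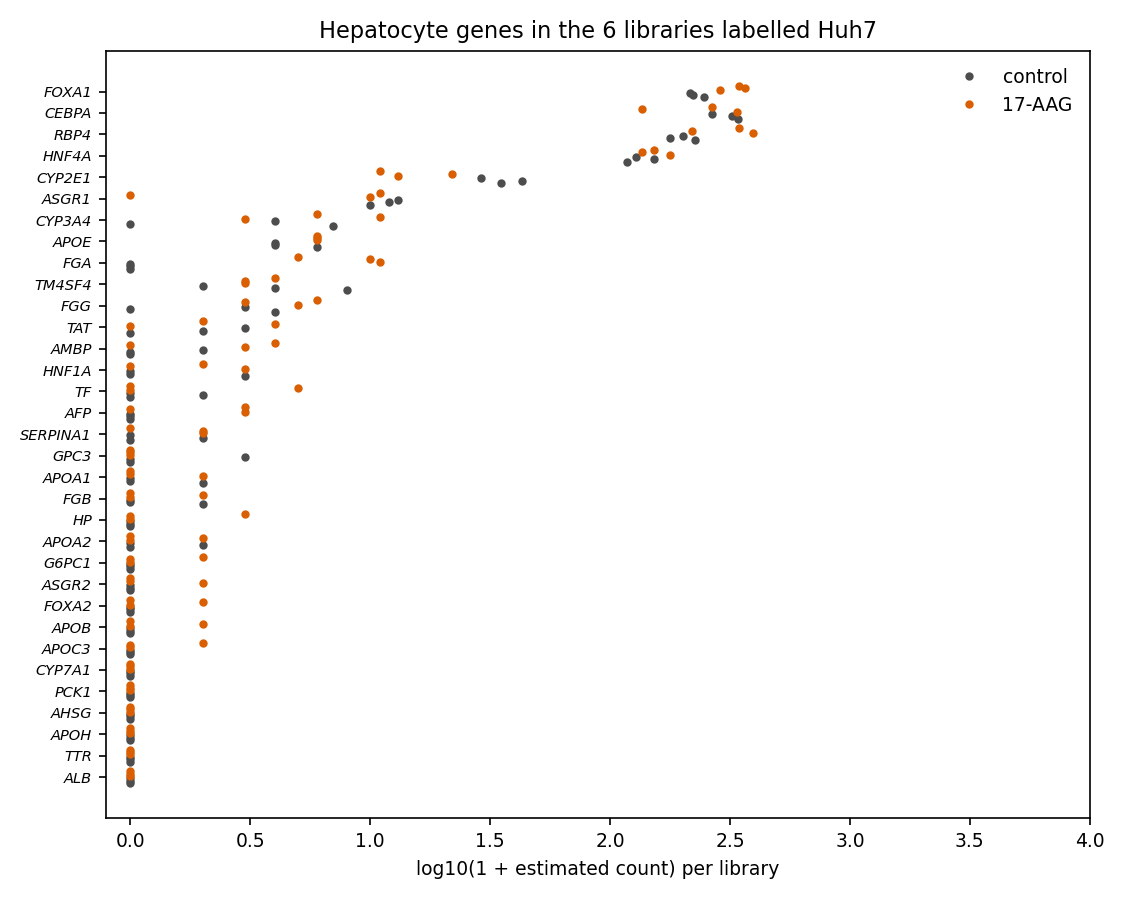
Estimated counts, as log10(1 + count), of 33 hepatocyte genes in each of the 6 libraries labelled Huh7 (grey, control; orange, 17-AAG; 1 point per library). ALB has 0 counts in each library, and 4 genes reach 1 CPM in all 6.

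Markers of other cell types were used to look for RNA from elsewhere. Of 18 immune and blood cell markers 17 lay below 1 CPM in all 6 libraries; the exception, the lysosomal protein gene CD68, rose 2.10-fold to 71.1 ± 20.6 CPM and was the list's only tested member. Of 8 tested stromal and endothelial markers 4 rose and 3 fell, also over the list alone (median 0.50; camera adjusted p = 0.426). CDH5, the endothelial cadherin, went from 0.680 ± 0.0340 to 7.30 ± 0.564 CPM and COL3A1 from 1.21 ± 0.397 to 7.54 ± 0.326 CPM, whereas LUM (lumican), the most abundant tested member, fell from 89.0 ± 3.64 to 75.2 ± 4.17 CPM and DCN from 10.9 ± 0.269 to 3.61 ± 0.729 CPM; COL1A1 rose 1.41-fold. Of 7 tested cholangiocyte and progenitor markers 3 rose and 1 fell (4 and 2 over the list alone; median 0.53, camera adjusted p = 0.426), with CD24 3.23-fold higher at 137 ± 9.71 CPM and SOX4 1.79-fold lower. KRT7, a keratin of simple ducts, stood at 651 ± 10.6 CPM in the controls and 556 ± 153 CPM with 17-AAG (adjusted p = 0.314). Of the 12 markers listed, 5 reached 1 CPM in all 6 libraries and 5 lay below it in all 6. Among the latter, the keratin gene KRT19 had 5 counts in all and CFTR 3.

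With an estimated correlation between genes none of the 13 sets called by camera kept its call, and camera tests a set against the other genes, of which many also changed. On counts simulated for this comparison over the 12429 genes, the test recovered 46 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 9 false calls.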

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

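Tests on 17-AAG replicate 1 alone, length and GC trends and mitochondrial genes left out were chosen after the data were seen. The count of 6359 changed genes lay between 4635 and 7762 when a library was left out (1069 to 1488 at least 2-fold, 2272 to 3891 higher, 2362 to 3871 lower, 12 to 14 gene lists, 7 to 8 of the 8 genes of the study's question); without 17-AAG replicate 2, whose mitochondrial share was highest, 7762 were called, and 6277 of the 6359 were among them. With 17-AAG replicate 1 alone it was 7514, but there only the controls, which differ little from each other, give a spread, so that count supports none of the calls. It was 7041 with length and GC trends removed (5886 shared), 6408 with DESeq2 (6141 shared) and 6412 with limma-voom, and the genes shared with each alternative kept their direction. At an adjusted p below 0.01 it was 4031. The direction of change moved most with the scaling: 2155 genes were higher under library size alone and 1755 with the replicate block added to it. Deviations of same-numbered libraries correlated at 0.00381, -0.00869 and -0.0410, and no 17-AAG library correlated best with the control of its own number. The replicate numbers showed no sign of pairing the samples, but the controls differed little from each other, so a pairing could be missed. With the replicate number as a block 5922 genes were called, 5764 of them shared. The block also ended the call of the cholesterol list (adjusted p = 0.102, and 0.0756 with length and GC trends removed as well). The number of lists called was 13 with the preset correlation, 0 with an estimated correlation and 21 with fry, which tests whether a list's genes move one way and does not compare them with other genes.

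Lists near 0 changed direction under the settings below without being called; of the values without a library, those with a changed direction are named. For lipid droplet proteins the adjusted p was 0.991075 with the replicate block, 0.670662 with 17-AAG replicate 1 alone, 0.709827 with length and GC trends removed and 0.740186 with the block as well, and 0.6283 to 0.946367 without a library, where the direction changed without 17-AAG replicate 2 (0.6283) and with no other library left out. For proteasome subunits it was 0.873752 by fry and 0.729262 with 17-AAG replicate 1 alone. For apoptosis regulators it was 0.899297 by fry, 0.969909 with the block, 0.802881 under library size alone, 0.864862 with length and GC trends removed, 0.851137 with the block as well, and 0.859197 to 0.989605 without a library, where it changed except without 17-AAG replicate 3 or control replicate 3. For glycolysis and hypoxia it was 0.729262 with 17-AAG replicate 1 alone, 0.974692 and 0.981068 with length and GC trends removed without and with the block, and 0.607067 to 0.849846 without a library, where it changed without 17-AAG replicate 2 (0.768095) and with no other library left out. The cause of these changes was not tested. Of the genes the naming rule took and that are reported here, HSF1, DNAJB1, GLB1, CDKN2C, MGLL, HNF4A, CYP2E1 and COL1A1 lost their call under at least 1 alternative, and none changed direction. Log2 fold change correlated across genes with transcript length (Spearman 0.165) and GC content (-0.186); genes are not independent replicates. Simulated 1.5-fold changes were recovered in 68.7% of cases, with few changed genes and the same spread in both groups. The share in these data may differ, and small changes can be missed. Depth and number of libraries were not varied.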

Other observations

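The families in this part, and the tests of the hepatocyte pattern, of the G1/S list and of the number of changed genes over other splits, were chosen after the data were seen. Some families hold genes already described, so each was tested with camera whole and, later, without the genes of the fixed lists, the check genes, the largest rises and falls and the abundant genes looked at first. The first test had already used the genes of the second, so the second is not a fresh test of unseen genes. Whole, 7 of 8 tested families passed, and 3 of 8 passed in the second test, whose adjusted p-values are given here; with an estimated correlation 0 of 8 passed in either test; counts are for whole families. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 15 fell and 2 rose (median log2 fold change -0.53; 17 genes tested, adjusted p = 0.000889, and adjusted p = 0.218 with an estimated correlation), among them MARS1, AARS1 and SARS1 with log2 fold changes of -1.19, -1.06 and -0.93. Nuclear genes of the respiratory complexes went opposite to the mitochondrially encoded ones, with 37 of 48 lower and 0 higher (median -0.51, adjusted p = 5.10e-07, and adjusted p = 0.218 with an estimated correlation). UQCRH and NDUFA4 had log2 fold changes of -0.89 and -0.84. The family's median log2 difference from the controls was -0.34, -0.63 and -0.59 in 17-AAG replicates 1, 2 and 3. Over all genes with a length, such differences correlated with transcript length at Spearman 0.115, 0.226 and 0.113 in those libraries. Length and GC trends were not removed for any family of this part. Of 18 genes of serine, glycine and one-carbon metabolism, 11 fell and 1 rose, PSPH, SHMT2 and PHGDH with log2 fold changes of -1.55, -1.20 and -1.11, but the 11 genes not described before did not pass as a set (median -0.22; adjusted p = 0.0607, against 0.000258 whole, or 0.115 whole with an estimated correlation). Nor did 51 mitochondrial ribosomal protein genes, of which 20 fell and 5 rose (median -0.14; adjusted p = 0.0607, against 0.0433 in the first test with the same genes, as the correction over families differed, or 0.238 there with an estimated correlation).

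Tubulin genes rose in 10 of 12 cases and fell in 1 (median 0.74; 11 genes tested, adjusted p = 0.000889, and adjusted p = 0.218 with an estimated correlation), including TUBA1B, TUBA1C and TUBB4B with log2 fold changes of 1.00, 1.17 and 0.99, while the chaperonin and prefoldin genes that fold tubulin and actin had a median of -0.08 (1 of 14 higher, 3 lower; adjusted p = 0.506). Keratin and squamous epithelial genes rose in 7 of 13 cases, among them DSP and KRT17, and fell in 1. The 10 kept in the second test did not pass as a set (adjusted p = 0.0993, against 0.0433 whole, or 0.280 whole with an estimated correlation). Of 9 placental and germ-cell genes 5 rose, but CGA and SPANXB1 were among them and were left out of the second test. Of the 5 kept in it, 1 rose and 0 did over the family alone (median 0.14, adjusted p = 0.529, against 0.00305 whole, or 0.238 whole with an estimated correlation). ALPP, placental alkaline phosphatase, went from 50.8 ± 1.15 to 226 ± 40.4 CPM (SD, n = 3 each); ALPG is a near-identical copy of it. Of 4 metallothionein genes 1 rose, MT1X, and 1 fell, MT1E.

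Cytosolic ribosomal protein genes were lower with 17-AAG, and these short, abundant transcripts would also fall with a length or GC trend between libraries or through the library with the highest mitochondrial share. With length and GC trends removed the median was -0.4042 (SE 0.0603 over members, against -0.4814 before). The length used was that of a gene's longest annotated transcript, for example 3647 bases for RPL37A and 2312 for RPL13A. Those lengths may exceed those of the transcripts expressed, so this value cannot decide whether a length or GC trend contributed. Without 17-AAG replicate 2 the median was -0.4253 (SE 0.0490), which argues against that library as the whole cause. A difference in RNA integrity or in the method of RNA selection was not tested and stays open. An effect of 17-AAG itself, which the design names, also stays open and was not tested separately.

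Mitosis and G2/M genes were higher while p21 transcripts were too. The median was 0.6129 with length and GC trends removed (SE 0.0903 over members, against 0.6083 before). These trends also rest on each gene's longest annotated transcript, so this value cannot decide whether a length or GC trend contributed. Without 17-AAG replicate 2 the median was 0.5853 (SE 0.0779 over members), which argues against that library as the whole cause. A general rise of cell-cycle genes would raise the DNA replication and G1/S list, whose median was -0.2149 (SE 0.0903 over members). That list went both ways, with 5 of 26 genes higher and 13 lower. All 10 tested replication-dependent histone genes rose (median 1.57), so the rise was not confined to the mitosis and G2/M list. An accumulation of cells in G2 or mitosis may account for the pattern, and no measurement of the cell cycle was used here to test it.

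Hepatocyte genes lay near the count floor although Huh7 cells are known to make albumin and alpha-fetoprotein. All 33 symbols of the list stand in the table, so missing rows do not account for it, and the highest control median was 0 CPM, so a loss under 17-AAG does not account for it. Only 4 of the 33 reached 1 CPM in all 6 libraries, which restates the pattern and supports no explanation of it. The keratin gene KRT7 stood at 651 CPM and CGA at 48.1 CPM in the controls. A line that had lost its hepatocyte programme, or cells other than those named in the labels, are candidate explanations that these libraries cannot separate.

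In the 10 ways of splitting the 6 libraries into 3 and 3, the real split gave 6359 changed genes, 3212 in the larger direction, 1168 changed at least 2-fold and 13 lists, and the highest of the other splits gave 0, 0, 0 and 9. In each case 1 split reached the real value, and 10 splits are too few for a share under 0.05. Every other split mixes treated and control libraries within a group, which widens the spread, so its gene count of 0 is no support for the real one. Those splits still called from 5 to 9 lists. Their groups hold unequal numbers of treated libraries, so part of the treatment difference remains in each. These calls therefore cannot show how often camera calls a list where no such difference exists.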
